A study of Mus musculus with 12 samples.

How the data were processed

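RNA of bone-marrow-derived macrophages from 12 female mice was measured on 12 Affymetrix Mouse Exon 1.0 ST arrays, 1 per mouse. Per the labels' protocols, the cells were differentiated with recombinant human M-CSF, oxLDL was given to 6 cultures at 25 ug/mL for 24 h, total RNA was isolated with TRIzol and its quality was checked on a Bioanalyzer. The values are expression levels on the log2 scale, summarised by the authors per transcript-level probe set, per the series' design text in the labels. PLIER and Affymetrix Power Tools are named in the submitters' processing notes, without versions. The order of their steps, the background correction, the normalization between arrays, the annotation version and the processing days are not given in the sources used here. The deposited table holds 74007 probe sets by 12 arrays with values from 5.89 to 14.5 and 0 missing values, and every column matched 1 sample.

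The probe sets carry Ensembl transcript IDs. The gene table given for names has 49997 entries, of which 0 hold an Ensembl ID, so no ID was paired with a gene name, and none was named from memory. Several IDs can read the same signal: 5192 IDs have values identical to another ID on all arrays, which leaves 71258 distinct profiles in the table and 38369 among those tested. An ID was said to follow another where their values, each centred on its own mean, differed by less than 0.15 on the log2 scale on every array.

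Arrays were put into 4 groups of 3 by the genotype and stimulus in the labels: WT unstimulated, WT with oxLDL, Atf3 knockout unstimulated and Atf3 knockout with oxLDL. The tests, alternatives, gene lists and the rule for named transcripts were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3: lmFit with a mean for each group over all 12 arrays, eBayes with an intensity trend, and Benjamini-Hochberg adjusted p under 0.05 with no threshold on fold change, for 5 contrasts. These were oxLDL against none in WT and in the knockout, knockout against WT without and with oxLDL, and the interaction, the knockout response minus the WT response. A probe set was tested if it lay above the median of the array on at least 3 of the 12 arrays, which kept 39620, or 53.5%. The fit has 8 residual degrees of freedom and a prior of 4.36, and the pooled residual SD was 0.20 on the log2 scale. Each adjusted p in the text is from limma over the tested probe sets of that contrast. Fold changes are 2 to the power of the log2 difference, with no pseudocount. Since 3 against 3 arrays cannot give an exact permutation p below 0.1, such a test was not used for single transcripts. The labels describe 12 separate mice, but whether samples of a group shared a culture, RNA pool or processing day is not given in the sources used here, so p-values measure the spread between these samples, part of which may be technical.

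The rule for named transcripts was, per comparison, the largest rises and falls among those with adjusted p under 0.05 whose 3 arrays of one group all lay above the 3 of the other; for the interaction, adjusted p alone. It was shortened from 10 per direction to 2 because the IDs carry no gene names. For the same reason 18 gene lists and 12 lists of cell type markers fixed in advance, their set tests, the levels of Atf3 and of another gene of interest, the restriction to probe sets with 1 gene symbol and the alternative of averaging the probe sets of a symbol were not run. Markers of other cell types were therefore not analysed here.

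The test was checked on simulated data made from the 39620 tested probe sets, 200 of them with known changes. With equal spread in all groups, 3.70% to 8.28% of calls in the 4 contrasts between groups were false, and 98.5% to 100% of log2 changes of 1 were recovered. With each group given its own observed spread, the 12-array fit gave 268 false calls among 411 for oxLDL in WT, 16 among 143 for genotype with oxLDL and 0 for the other contrasts between groups. With the same data and only the 6 arrays compared, false calls were between 0% and 4.31% in the 4 contrasts. The simulated noise had 1 SD for all transcripts of a group and was independent between transcripts. On the real arrays transcripts differed in spread, with a prior of 4.36 degrees of freedom, and many deviated together on 1 array. The simulated shares depend on this and on the number of changed transcripts. They do not carry over to the real lists, which are longer.

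Arrays of different groups share replicate numbers in the labels, but the labels describe separate mice, so no replicate block was used in the main test, and the check of pairing is given with the alternatives. Alternatives fixed in advance were no filter, a filter at the 25th percentile, quantile normalization, centring on array medians, 16 added to the unlogged values, eBayes without the trend or with a robust prior, array weights, the replicate number as a block, only the 2 groups compared, leaving out each array in turn, and, for overlaps, adjusted p under 0.1. Array weights were estimated gene by gene because the default algorithm did not converge and gave 1 array a weight of 1893. Chosen after seeing the data were 1 variance per group, 1 ID per set of identical values, both WT arrays that stood apart left out (unstimulated replicate 1 and oxLDL replicate 3), the WT response to oxLDL without unstimulated WT replicate 1 for a transcript named in another comparison, and the reading of calls from the knockout arrays alone in the WT arrays. Correlations of log2 changes across transcripts and overlaps of calls, with the overlap of independent lists as the product of their sizes over the number tested, also summed over 20 equal classes of the standard error (chosen after seeing the data), were computed between comparisons that share no array. Principal components were taken of the tested probe sets, centred and not scaled.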

Results

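Macrophages were grown from the bone marrow of 12 female mice on a C57BL/6J background, 6 wild type (WT) and 6 lacking Atf3, a transcription factor of the ATF/CREB family that is induced by cell stress. For each genotype, cells of 3 mice were left unstimulated and cells of 3 other mice were given oxidised low-density lipoprotein (oxLDL), human LDL oxidised with copper, at 25 ug/mL for 24 h. Macrophages take up oxLDL through scavenger receptors and become lipid-laden foam cells. The series addresses how transcription changes during this process and how loss of Atf3 alters it. Transcript levels were read on 12 Mouse Exon arrays, 1 per mouse, as log2 values for 74007 probe sets, each named by an Ensembl mouse transcript ID. The tables used here do not pair these IDs with gene names, so results are given by ID, and the level of Atf3 itself was not analysed here. Array medians lay between 8.42 and 8.57, and the number of arrays limits the precision of every value.

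The arrays separated first by genotype. The first principal component held 54.0% of the variance and placed the 6 Atf3 knockout arrays between 33.1 and 45.6, while 5 WT arrays lay between -56.1 and -38.9 and the remaining one, unstimulated WT replicate 1, lay at -0.58. The second component, with 22.2%, held mainly the difference between WT oxLDL replicate 3, at 76.6, and the other arrays. Stimulus appeared on the third component, with 14.0%, where the 6 unstimulated arrays lay between -38.0 and -12.2 and 5 oxLDL arrays between 15.1 and 35.2; WT oxLDL replicate 3 lay at -6.02.

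**Figure D1:**
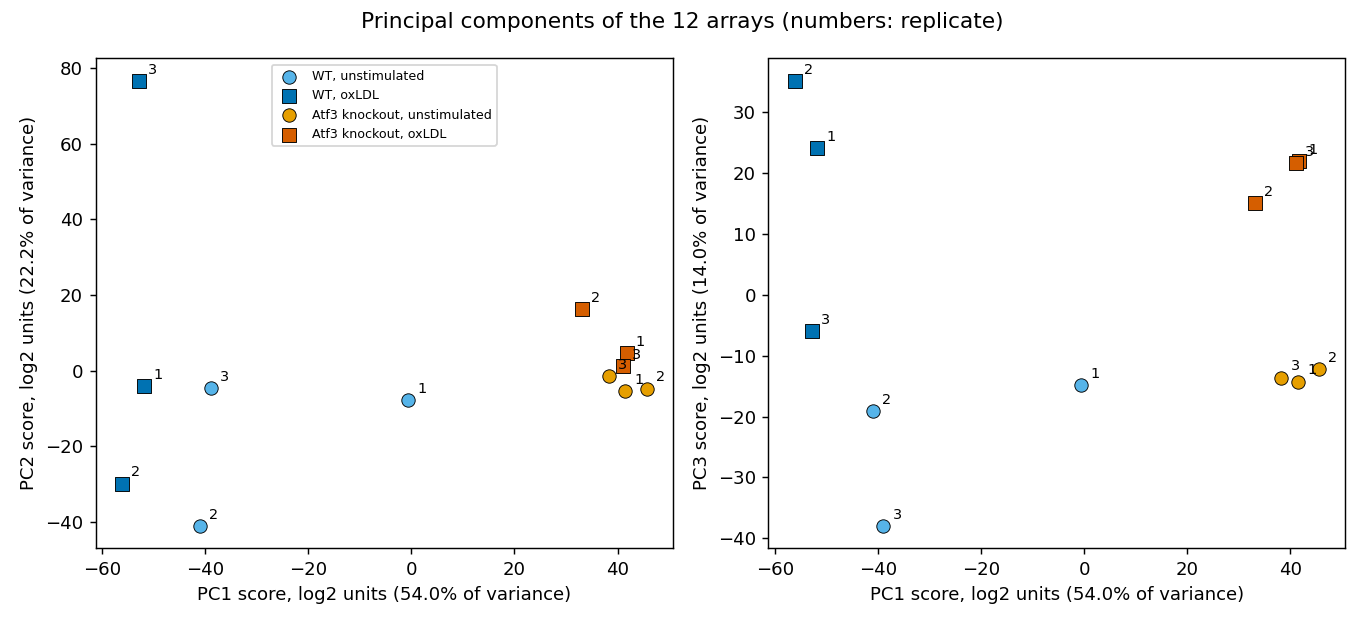
Scores of the 12 arrays on the first against the second and the first against the third principal component, in log2 units with the percent of variance on each axis; each point is 1 mouse, numbered by replicate, with colour and shape giving genotype and stimulus. The knockout arrays lie between 33.1 and 45.6 on the first component, and WT oxLDL replicate 3 stands apart at 76.6 on the second.

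Replicates of the knockout were far closer to each other than replicates of the wild type. The SD of an array's deviations from its group mean was 0.179 ± 0.0478 over the WT arrays (SD, n = 6) and 0.0574 ± 0.00788 over the knockout arrays (SD, n = 6), and the lowest WT array lay above the highest knockout array. No p is given for this difference, since each deviation is taken from a mean that holds the array itself and its group mates. Correlations between replicates, across transcripts, were 0.943 to 0.978 in unstimulated WT and 0.905 to 0.977 in WT with oxLDL, against 0.995 to 0.996 and 0.993 to 0.996 in the corresponding knockout groups. Unstimulated WT replicate 1 had a mean correlation of 0.954 with the unstimulated knockout arrays and of 0.946 with the other arrays of its own group. Because 1 limma fit over all 12 arrays shares its estimate of spread between the groups, counts from the arrays of the groups compared alone are given beside each count below where they differ by over 1.5 times. This separates the spread of the genotypes only for the oxLDL comparisons. The genotype comparisons still pool WT and knockout, with replicate SDs of 0.223 and 0.0671 without oxLDL and 0.315 and 0.0852 with it.

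**Figure D2:**
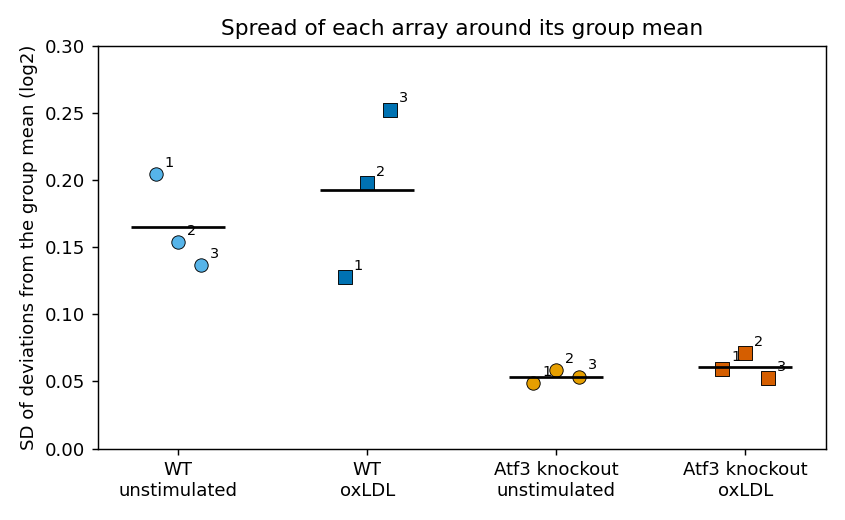
SD, in log2 units, of each array's deviations from the mean of its group over the tested transcripts; each point is 1 array, numbered by replicate, and bars are the means of the 4 groups. The knockout arrays lie at or below 0.0714, and the lowest WT array lies at 0.128.

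In WT macrophages, 24 h of oxLDL moved some transcripts by more than 4-fold. Transcript ENSMUST00000138220 rose 4.77-fold, from 10.86 ± 0.57 to 13.12 ± 0.34, and ENSMUST00000006392 rose 4.17-fold, from 7.91 ± 0.10 to 9.97 ± 0.12 (log2 mean ± SD, n = 3 arrays per group). The largest falls were those of ENSMUST00000038423, 7.15-fold from 11.10 ± 0.38 to 8.26 ± 0.41, and of ENSMUST00000127223, 6.18-fold from 11.06 ± 0.58 to 8.43 ± 0.65. Among the transcripts that passed the test, 96 rose and 371 fell by more than 1 on the log2 scale.

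In limma, 2844 of the 39620 transcripts tested, or 7.18%, had a Benjamini-Hochberg adjusted p under 0.05, 818 higher and 2026 lower with oxLDL. The adjusted p of the 4 named transcripts was 3.30e-04, 2.04e-07, 4.82e-05 and 4.93e-04, and with the 6 WT arrays alone they lay between 0.00160 and 0.0284. Those arrays alone gave 277 calls, 54 higher and 223 lower. In simulated data with each group's own SD, independent noise and 200 changed transcripts, the 12-array fit gave 268 false calls among 411 here. The 6-array fit gave 3 among 119. Neither share carries over to the real lists, whose transcripts differ in spread and deviate together. The balance of directions depended on scaling and on 1 array: quantile normalization gave 3265 higher and 3478 lower, and leaving out WT oxLDL replicate 3 gave 4968 higher and 2336 lower.

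In Atf3 knockout macrophages the largest changes with oxLDL were rises. Transcript ENSMUST00000149983 rose 3.55-fold, from 10.15 ± 0.12 to 11.98 ± 0.07, and ENSMUST00000029769 rose 3.34-fold, from 10.19 ± 0.10 to 11.93 ± 0.10 (log2 mean ± SD, n = 3 arrays per group). Both also rose in WT, by 1.70 and 1.65 on the log2 scale (limma adjusted p = 2.32e-04 for each). These IDs had nearly the same values on every array, so they count as 1 measurement. Transcript ENSMUST00000087904 fell by 1.59, from 9.68 ± 0.16 to 8.09 ± 0.18, and ENSMUST00000079824 fell by 1.58, from 10.83 ± 0.09 to 9.25 ± 0.15. In WT, ENSMUST00000087904 fell by 1.17 (adjusted p = 0.00408), and ENSMUST00000079824 had a change of -0.97 that did not pass (adjusted p = 0.0719) and rested in part on unstimulated WT replicate 1, without which it was -0.49 (SE 0.12, adjusted p = 0.0363). Its response was not shown to differ between the genotypes (interaction adjusted p = 1.00).

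In this comparison 604 transcripts, 1.52% of those tested, passed in limma, 239 higher and 365 lower, and 58 of these rose and 18 fell by more than 1 on the log2 scale. The adjusted p of the 4 named transcripts was 5.56e-04, 5.56e-04, 0.00377 and 0.0187. The 6 knockout arrays alone gave 9896 calls, 5576 higher and 4320 lower. In simulated data with each group's own SD and independent noise, that fit recovered 100% of log2 changes of 0.5. The 12-array fit recovered 2.99%. These recoveries do not carry over to the real arrays. No source used here says whether the knockout samples shared RNA, culture or day. If they did, the 9896 calls do not measure the spread between mice. Leaving out any 1 of the 6 arrays left 106 to 224 calls, and the balance of directions depended on the array. Without unstimulated knockout replicate 1 or 2 rises outnumbered falls, 65 against 41 and 71 against 46. Without knockout oxLDL replicate 2 they did so by 97 against 53. Falls outnumbered rises without unstimulated knockout replicate 3, 137 against 87, and without knockout oxLDL replicate 1, 87 against 73. Each of the 6 fits took the adjusted p of ENSMUST00000079824 above 0.05, with a change of -1.63 to -1.49 against -1.58. With the 6 knockout arrays alone the adjusted p of ENSMUST00000079824 was 5.59e-07.

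The responses of the genotypes to oxLDL, measured on separate arrays, shared many transcripts. Of the transcripts called in WT and in the knockout, 191 rose in both, where 4.93 would be shared by independent lists of those sizes, and 348 fell in both, where 18.7 would be shared; no transcript was called in opposite directions. Both lists use the same standard error per transcript, and within classes of like standard error the values for independent lists were 5.52 and 18.8. Across all tested transcripts the log2 changes in WT and knockout had a Pearson r of 0.742 and a Spearman rho of 0.612, and 69.1% had the same sign. Over the 2909 transcripts called in either genotype, r was 0.874 and 98.1% had the same sign. Transcripts are not independent replicates, and these correlations describe the 12 arrays only.

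**Figure D3:**
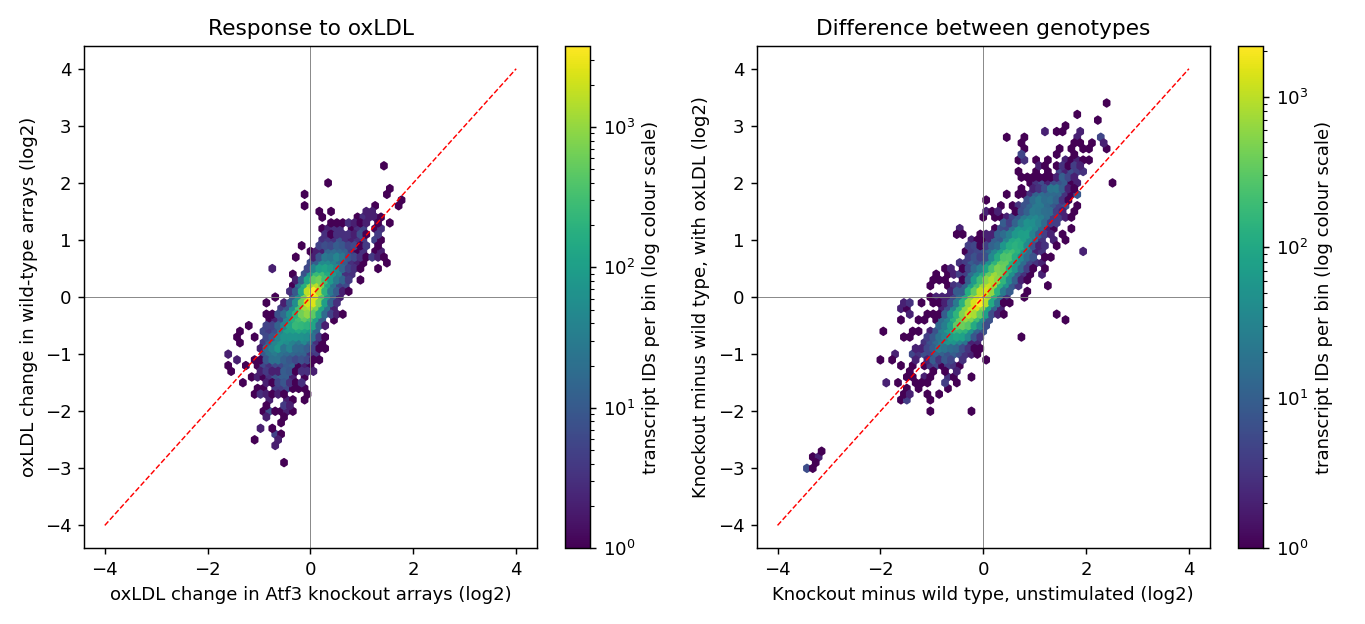
Log2 changes of the 39620 tested transcripts, as counts per hexagonal bin on a log colour scale; left, response to oxLDL in knockout arrays (x) and WT arrays (y), and right, knockout minus WT without (x) and with (y) oxLDL, with a dashed line of equal change. Pearson r is 0.742 on the left and 0.906 on the right, and no array enters both axes of a panel.

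Without stimulus, knockout and WT macrophages already differed in many transcripts. Transcript ENSMUST00000023248 was 5.63-fold higher in the knockout, at 11.49 ± 0.07 against 9.0 ± 0.23, and ENSMUST00000050562 was 5.45-fold higher, at 11.20 ± 0.07 against 8.75 ± 0.26 (log2 mean ± SD, n = 3 arrays per group). The largest deficits in the knockout were those of ENSMUST00000079443, 10.8-fold, at 8.20 ± 0.03 against 11.63 ± 0.89, and of ENSMUST00000112108, 10.7-fold, at 8.13 ± 0.03 against 11.55 ± 0.89. These belonged to a family of IDs with nearly the same values on every array, in which 6 other IDs followed each, so they are not separate measurements. Among the transcripts that passed the test, 735 were higher by more than 1 on the log2 scale and 115 lower in the knockout.

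In limma, 6640 transcripts, 16.8% of those tested, passed, 4510 higher and 2130 lower in the knockout, and the adjusted p of the 4 named transcripts was 1.25e-05, 1.14e-04, 2.16e-04 and 2.16e-04. Quantile normalization gave 12241 calls, 5966 higher and 6275 lower, centring on array medians gave 5299 higher and 4563 lower, and the 6 arrays alone gave 5655 higher and 4201 lower, while leaving out 1 array gave 2797 to 8863 calls. The labels used here give no processing day or batch, so a day shared by the arrays of a genotype cannot be told apart from genotype in this comparison or the next.

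With oxLDL, knockout and WT macrophages again differed in many transcripts. Transcript ENSMUST00000050562, which fell by 1.28 with oxLDL in WT (adjusted p = 0.00285) and changed by -0.32 in the knockout (adjusted p = 0.918), a difference of responses that did not pass (0.97, interaction adjusted p = 1.00), was 10.7-fold higher in the knockout, at 10.88 ± 0.14 against 7.47 ± 0.51 (log2 mean ± SD, n = 3 arrays per group). Transcript ENSMUST00000092836 was 9.08-fold higher, at 11.78 ± 0.14 against 8.60 ± 0.31. On the knockout arrays ENSMUST00000050562 lay at 10.72 to 10.98 with oxLDL, below the 11.12 to 11.25 without it. The limma adjusted p of 0.918 uses a spread shared with WT, so it does not show that the knockout lacked a response. The lowest in the knockout were again members of the family described above, ENSMUST00000112107 at 8.05 ± 0.02 against 11.09 ± 0.40 and ENSMUST00000112108 at 8.07 ± 0.02 against 11.12 ± 0.40, each 8.2-fold lower. Among the transcripts that passed the test, 1695 were higher by more than 1 on the log2 scale and 126 lower in the knockout.

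In limma, 11427 transcripts, 28.8% of those tested, passed, 7896 higher and 3531 lower in the knockout, and the adjusted p of the 4 named transcripts was 6.11e-06, 2.18e-04, 9.46e-05 and 9.46e-05. The 6 oxLDL arrays alone gave 7477 calls, 5765 higher and 1712 lower, and leaving out oxLDL knockout replicate 1 or 3 gave 7235 or 7352. The split of directions turned with quantile normalization, to 8586 higher and 9360 lower, and without WT oxLDL replicate 3, to 19771 calls, 8010 higher and 11761 lower, and it narrowed to 8452 higher and 6584 lower with centring on array medians.

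Many of the same transcripts differed between the genotypes with and without oxLDL. Of the calls, 4281 were higher in the knockout in both states, where 899 would be shared by independent lists, and 1583 were lower in both, where 190 would be shared, with none in opposite directions. Within classes of like standard error, which both lists share, the values for independent lists were 922 and 201. Across all tested transcripts the differences between genotypes in the 2 states, which share no array, had a Pearson r of 0.906 and a Spearman rho of 0.876.

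One transcript passed the test of a different response to oxLDL in the genotypes, and the number that passed depended strongly on the settings. ENSMUST00000006392 rose by 2.06 on the log2 scale in WT (SE 0.08) and had a change of 0.35 in the knockout (SE 0.08, adjusted p = 0.0610), where it went from 7.67 ± 0.06 to 8.02 ± 0.04 (SD, n = 3 arrays per group). Its knockout arrays lay at 7.98 to 8.06 with oxLDL, above the 7.62 to 7.74 without it. That adjusted p uses a spread shared with WT, so a smaller rise in the knockout is not excluded. The difference of the responses was -1.71 (SE 0.12, limma adjusted p = 1.18e-04 for the interaction), and each WT array with oxLDL lay above all the others. Next by p and not passing was ENSMUST00000038423, which fell by 2.84 in WT and changed by -0.52 in the knockout (interaction 2.32, SE 0.30, adjusted p = 0.0562). At an unadjusted limma p under 0.05 there were 1149 transcripts, 2.90% of those tested. This is less than the share of 0.05 that p-values with no interaction anywhere would give on average. Quantile normalization gave 16 calls, among them ENSMUST00000006392, and all 16 had the smaller response, in size, in the knockout. WT replicates spread more widely, so a selection on the difference of responses favours transcripts with a large WT response. The shared direction is therefore not separate evidence of a weaker response in the knockout. Centring on medians gave 5 calls, and leaving out 1 array gave 1 to 17, the highest without WT oxLDL replicate 3. Leaving out this array and unstimulated WT replicate 1 gave 109. Array weights gave 387, in a fit whose WT oxLDL mean rests mainly on replicate 1. A count of 1 therefore does not show that the other responses were alike.

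**Figure D4:**
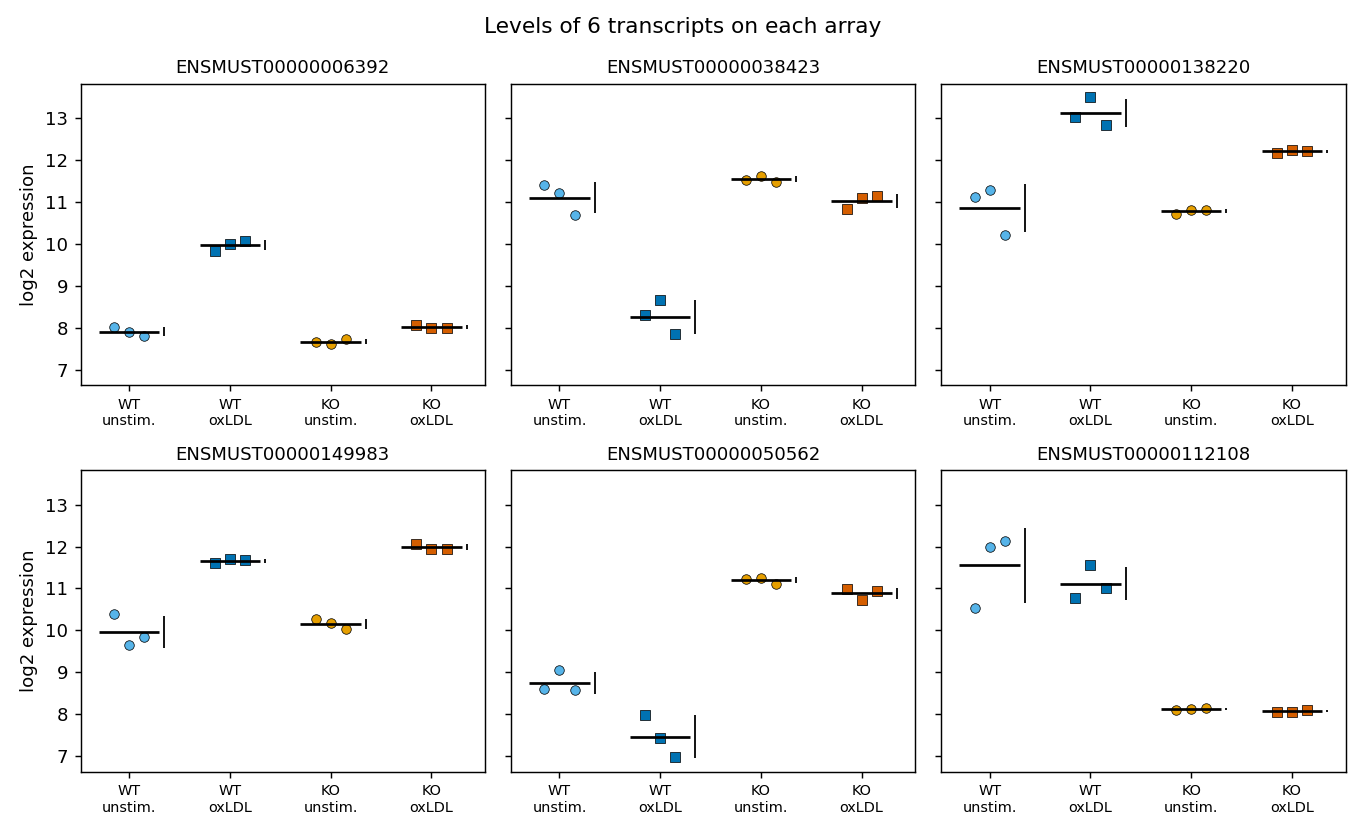
Log2 expression of 6 named transcripts on each of the 12 arrays; points are arrays (1 mouse each), horizontal bars are group means and vertical bars are 1 SD to either side of the mean (n = 3). ENSMUST00000006392 reaches 9.97 in WT with oxLDL and 8.02 in the knockout with oxLDL, and ENSMUST00000112108 lies near 8.1 in both knockout groups.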

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

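The tests of a single deviant array, of array scale, of shared RNA or processing and of a wrong label, and the count of the other split after quantile normalization, were chosen after the result was seen, whereas those of noise in dim probe sets, of mixed RNA and of other splits of the arrays were set before their outcome was known.

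The response of ENSMUST00000006392 to oxLDL differed between the genotypes, with a difference of -1.71 on the log2 scale, knockout minus WT, in the test of the interaction. It rose by 2.06 in WT and had a change of 0.35 in the knockout. Of 100 splits of stimulus within genotype, the real one included, 27 gave at least 1 call, and the highest other gave 3949. A split that mixes or reverses the labels in 1 genotype turns the oxLDL response shared by both genotypes into a difference of responses. These splits therefore cannot decide whether this count is due to chance, and chance is not excluded.

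The replicate SD within groups, as a root mean square over transcripts and both groups of a genotype, was 3.56 times as high in WT as in the knockout, and the ratios below are of this quantity. A single deviant array, WT oxLDL replicate 3, is not the whole cause, since the unstimulated groups, which lack it, have a ratio of 3.32, and array scale is not either, since the ratio stays at 3.31 after quantile normalization. Noisier measurement on the WT arrays stays open. In the dimmest 18502 probe sets the ratio was 1.55, which narrowly met the level set in advance as a sign of this cause. Leaving out any 1 WT array, a check outside that rule, gave 1.41 to 1.79, the lowest being under that level. In the brightest 18502 probe sets the ratio was 3.97. Knockout samples that share RNA, culture or day cannot be told apart from mice that truly vary less, because no label gives such a link; the lowest correlation between knockout replicates was 0.993. A difference in how far WT and knockout mice vary is a possible biological reading, and it was not tested.

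Unstimulated WT replicate 1 lay between the genotypes. Its position was read from the other unstimulated WT arrays at 0 to the unstimulated knockout at 1. The transcripts used differed between genotypes by more than 1 on the log2 scale with oxLDL. They also differed by more than 0.5 between these unstimulated reference arrays. The median position was 0.55 for transcripts higher in the knockout and 0.23 for those lower. This speaks against a wrong label but does not exclude one, since a batch effect on this array stays open. Knockout RNA mixed into it should give 1 fraction in both directions on the unlogged scale, but the fractions were 0.445 (95% bootstrap interval 0.426 to 0.468, 1646 transcripts) and 0.30 (0.0722 to 0.374, 117 transcripts), a difference of 0.144 (0.0676 to 0.368), which speaks against mixing as the whole cause with the other two WT arrays as the reference. A ratio of medians gave a difference of 0.274 (0.138 to 0.394). All these intervals resample groups of transcripts with like profiles, not mice. The 1646 transcripts formed 1081 such groups and the 117 formed 76. A batch shared with the knockout arrays, with which it had a mean correlation of 0.954, cannot be told apart from a difference between mice, because no label gives a batch.

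Genotype separated the arrays along the component with 54.0% of the variance. Array scale alone is not the cause of the large number of calls, since quantile normalization gave 17946 with oxLDL against 11427 as deposited. A processing batch that follows genotype cannot be told apart from loss of Atf3 or from other differences between the mouse lines, because each genotype may have been handled on its own day and no label says.

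For the comparisons of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. For oxLDL in the knockout, genotype without oxLDL and genotype with oxLDL the real counts were 604, 6640 and 11427. The highest other was 0 in each, and 1 of 10 splits, the real one, gave as many. Every other split sets arrays of both kinds in each group, so a large real difference widens the spread and leaves few calls. The count of 0 is therefore not added support for these differences. For oxLDL in WT the real count was 2844 and 2 of 10 splits gave as many, the highest other being 10589. That split set unstimulated WT replicates 1 and 3 and WT oxLDL replicate 3 against the rest, several times the real count, which points to a structure among the WT arrays other than stimulus. These 3 arrays had interquartile ranges of 1.86, 1.78 and 1.51 against 1.87 to 2.05 on the log2 scale. Unstimulated WT replicate 1, at 1.86, and WT oxLDL replicate 1, at 1.87 on the other side, were nearly alike, so the split follows array width only in part. After quantile normalization the split gave 1570 calls against 6743 for the real one.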

How the results depend on the processing

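The fits with 1 variance per group, with 1 ID per set of identical values and without both WT arrays that stood apart, and the repeats of the correlation across arrays and normalization, were chosen after seeing the data. Counts are given in the order oxLDL in WT, oxLDL in the knockout, genotype without oxLDL, genotype with oxLDL and interaction, against 2844, 604, 6640, 11427 and 1. Quantile normalization gave 6743, 1843, 12241, 17946 and 16, and centring on medians gave 4622, 1199, 9862, 15036 and 5. Gene-by-gene array weights gave 5512, 15235, 12811, 28268 and 387. In that fit WT oxLDL replicate 1 had a weight of 4.03, against 0.267 and 0.0628 for replicates 2 and 3. The WT oxLDL mean therefore rests mainly on replicate 1, and the counts that use it are close to a comparison with 1 array. Only the 2 groups compared gave 277, 9896, 9856 and 7477, and 1 variance per group gave 712, 10323, 10627, 7471 and 2. Without both WT arrays that stood apart, counts were 8362 (5500 higher, 2862 lower), 3580, 18734 (9281 higher, 9453 lower), 22300 (9007 higher, 13293 lower) and 109. Leaving out 1 array gave 2116 to 7304, 106 to 224, 2797 to 8863, 7235 to 19771 and 1 to 17, the highest being without WT oxLDL replicate 3 for oxLDL in WT, genotype with oxLDL and the interaction; genotype without oxLDL fell to 3380 and 3669 without unstimulated WT replicates 2 and 3 and to 2797 to 3601 without any 1 unstimulated knockout array, genotype with oxLDL fell to 7235 and 7352 without knockout oxLDL replicates 1 and 3, and the interaction gave 3, 4, 5 and 9 without unstimulated WT replicates 1 and 3 and WT oxLDL replicates 1 and 2. The cause was not tested, except that fits that do not pool spread across genotypes remove the shared estimate by construction. The filters, the added 16, the prior settings and 1 ID per profile kept the 5 counts within 1.5 times.

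With the replicate number as a replicate block the counts were 2828, 552, 6798, 11588 and 1. Same-numbered arrays did not deviate together as a rule: 3 of 12 pairs had a correlation over 0.1, with a range of -0.314 to 0.512, the highest being that of the WT arrays numbered 2. Of 328 alternative values for the 17 named changes, 322 kept direction and call, 6 no longer passed, all for ENSMUST00000079824 in the knockout with 1 array left out, and 0 reversed. The named changes were picked in these data as the largest that passed, and the alternatives reuse the same arrays. The tally is therefore not separate support, and IDs with nearly the same values count more than once in it. The correlation of the oxLDL responses was 0.874 over called transcripts, 0.733 after quantile normalization and 0.670 to 0.787 with 1 array left out, against 0.742. At adjusted p under 0.1 the shared calls were 297 and 543 for oxLDL, higher and lower, and 2745 for lower genotype calls. Not run for lack of gene names were the mean per symbol and the alternatives for gene lists. No detection calls were used, so signal over background was not measured; changes in dim probe sets are limited by it.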

Other observations

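The reading of the knockout calls in the WT arrays and the tests of the genotype difference along the oxLDL response were chosen after the result was seen.

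The knockout arrays, with their small spread, gave a wider list of oxLDL-responsive transcripts, which was read in the WT arrays. If the knockout samples shared RNA, culture or day, which the labels leave open, those calls do not measure the spread between mice. Of the 5576 transcripts that rose in the knockout arrays alone, 82.9% had a rise in the WT means, with medians of 0.22 in the knockout and 0.20 in WT on the log2 scale. Of the 4320 that fell, 97.0% had a fall in the WT means, with medians of -0.29 and -0.45. The median of the falls in WT was -0.31 without WT oxLDL replicate 3 and -0.35 after quantile normalization, and that of the rises was 0.34 without that array, so these medians depend on 1 array. So do the shares: without it, 92.1% of the rises and 89.3% of the falls had the same sign in WT. The 88 calls with a change over 1 in the knockout arrays, 67 higher and 21 lower, all had the same sign in WT. In the other direction, 98.2% of the 277 calls from the WT arrays alone had the same sign in the knockout, and 52 of its 54 rises and 206 of its 223 falls were calls of the knockout arrays alone in that direction, where independent lists would share 7.60 and 24.3.

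One hypothesis was that the difference between genotypes runs along the oxLDL response, with unstimulated knockout cells partly moved towards the stimulated state, or knockout cells with oxLDL lagging behind it. The first predicts a positive and the second a negative correlation across transcripts of the genotype difference, in that state, with the response of the knockout; 1 knockout array was used in the difference and the other two in the response, so that no array was on both sides. Over the 39620 tested transcripts the mean Pearson r of the 3 choices was 0.0367 without oxLDL (0.010 to 0.0839) and -0.0681 with oxLDL (-0.0941 to -0.0165). Without unstimulated WT replicate 1 the mean for the unstimulated state was 0.0822, and the highest of its 3 choices was 0.129. With oxLDL the lowest of the 3 choices was -0.10 after quantile normalization, and -0.101 without WT oxLDL replicate 1 and without replicate 2. The mean slope of the genotype difference on the response was 0.0715 without oxLDL and -0.166 with it. With 1 WT array of that state left out it was 0.00943 to 0.187 and -0.181 to -0.151. A deviation shared by all arrays of a knockout group would still be on both sides, and it pulls each r away from the predicted sign. Unless such a deviation is large, these values speak against either as an account of the whole genotype difference. A shift along the response stays open, and its size is not settled.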
